A study of Drosophila melanogaster with 2 samples.

How the data were processed

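Chromatin immunoprecipitation and sequencing were performed on embryos of mixed sex, 0 to 24 h old, per the labels, with chromatin sonicated to 200 to 800 bp. The labels place both samples in 1 group and number them biological replicates 3 and 1, so no comparison between conditions exists. Each list is in narrowPeak format. Column 7 is a signal value per peak, and per the labels the authors computed it for each replicate, and for both pooled, with the same control alignment on each assembly. Its scale is not given in the sources used here, so it was used to rank and describe peaks within a list, and ratios of it between lists are descriptive only. Column 9 is the authors' −log10 q value, which sat at its maximum of 3.82 for all 2426 IDR peaks on dm6 and was therefore not used to rank them. The deposited summit offset in bp gave each peak's position. The aligner, the peak caller, their versions, the IDR threshold and the read depth are not given in the sources used here, and the depth of each sample is unknown. The replicate and pooled lists each stop at exactly 30000 regions and so include background, per the labels' description of them as input for IDR. The optimal IDR list was checked against the pooled list and was its 2426 strongest regions, with the same summits and signals.

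The lists on dm6 were used with the Release 6 genome sequence and Ensembl release 115 annotation (BDGP6.54), whose arm lengths contain every dm6 region. No coordinates were converted between assemblies, and dm3 regions were not annotated. Shifts on dm3 took the end of the last region as the arm length. A planned rank correlation of signals in order of rank between assemblies was left out, since sorting fixes it at its maximum. Counts per arm, and summits on 2L at identical positions, were compared in its place.

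Peaks were assigned to the classes promoter (500 bp either side of any of 19607 annotated protein-coding start sites), 5′ untranslated, 3′ untranslated, coding exon, intron and intergenic, in that order. Expectations came from 1000 circular shifts of the summits within each arm, with a two-sided p whose smallest value is 0.002. A gene held a peak if an IDR summit lay within 500 bp of any of its start sites. Gene lists and arms were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 26 lists. Genes that share a promoter share a peak and are not fully independent. In 10 cases an older symbol in a list was matched to its current one through RefSeq synonyms. This was done after the list tests had been seen once without it, and the same 5 lists passed either way. Shares carry 95% Wilson intervals. Replicate signals were correlated with 100000 permutations.

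Motifs were counted on both strands within 100 bp of a summit and 8-mers within 50 bp. Controls were pooled-list regions over 1000 bp from any IDR peak, sampled to match promoter class and GC quintile. Up to 5 per peak were planned, but thinning every stratum alike left 7896 of 25891, or 3.25 per peak. The 8-mers were first tested on chromosome 2, and the 20 best were retested on the other chromosomes. A retested word was counted only if it moved in the same direction, a requirement added after the retest had been seen once.

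Named genes followed a rule set before the data were examined: the gene with the nearest start site for each of the 25 strongest IDR peaks, CG12236, the 4 members of highest signal with a peak in each list that passed, and up to 2 in each other list. Other genes, including ush as host of a peak, HisRS, HisCl1, HisT and those named first in the closing section, were chosen after their values were seen.

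The tests were tested on simulated data. With shifted peaks, 1 of 20 promoter tests and 1 of 520 list tests made a call. The promoter tests drew their peaks as their background is drawn, so they cannot show whether shifted summits suit real peaks as a background. A planted list of 200 genes with peaks at 25% against 10% of others was recovered in 20 of 20 simulations. The fixed lists held 8 to 180 genes, so this does not give the power for them, least of all for the small ones. An 8-mer planted in 2% of 2426 simulated peak windows passed the first step in 16 of 20 simulations and the retest in 20 of 20, and in 4% it passed both in 20 of 20. That power does not carry over to words that background regions also hold. On chromosome 2, AACAAACA missed the first step at 4.07% of summits against 1.68% of matched regions (Fisher's exact test, adjusted p = 0.753). Alternatives included other distances, TSS windows of 200 and 1000 bp, 1 start site per gene, the 1213 strongest peaks, each replicate alone, other backgrounds and dm3. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.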

Results

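The data described where a tagged zinc finger protein met chromatin in whole Drosophila melanogaster embryos. Transgenic flies expressed CG12236, a BTB domain zinc finger protein, fused to enhanced green fluorescent protein (eGFP), and chromatin was immunoprecipitated with an antibody against GFP from embryos of both sexes collected 0 to 24 h after laying. There was 1 group of 2 biological replicates, numbered 3 and 1 in the labels. Each replicate had its own ranked list of 30000 regions, a further 30000 regions came from both replicates pooled, and the authors' optimal list by irreproducible discovery rate (IDR) held 2426 peaks on dm6, which were the 2426 strongest regions of the pooled list. No read totals were used here, so the depth behind each list is unknown. The signal of a peak is the authors' own value, and its level differed between the replicates. The intervals given below cover counting error only, and no control list was analysed, so backgrounds below come from shifted peaks, other genes, weaker regions of the same experiment or sequence beside the peaks. Coordinates are 1-based on dm6.

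The first comparison asked how far the replicates found the same peaks. The strongest peak of the IDR list, in an intron of ush at 2L 480883 to 481316, ranked 4 in replicate 1 with a signal of 319 and 1 in replicate 3 with a signal of 748. All of the 25 strongest IDR peaks ranked 37 or better in replicate 1 and 28 or better in replicate 3. Among the 2426 strongest peaks of replicate 1, 1632 (67.3%, 95% Wilson interval 65.4 to 69.1%) had a summit within 200 bp of a summit among the 2426 strongest of replicate 3, against a mean of 17.4 after circular shifts. The two-sided p of 0.002 is the smallest that 1000 shifts can give. Shifted summits lose the preference for promoters, which held 47.4% of these peaks in replicate 1 and 44.7% in replicate 3. The test therefore shows more overlap than random placement, but not that the shared peaks are specific to the tagged protein. Across the 2419 IDR peaks matched in both replicates, signal had a Spearman rho of 0.563 and a Pearson r of 0.67 on the log2 scale, each with a permutation p of 1e-05, the smallest possible. Leaving out the 2 peaks farthest from the median in replicate 1 gave a Pearson r of 0.66. These correlations are across peaks, which are not independent replicates, and the peaks were those strongest in the pooled list, to which both replicates contribute. Their ranks reached down to 29095 in replicate 1 and 9771 in replicate 3. The replicates also shared 1 control alignment, so part of their concordance can come from it.

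**Figure D1:**
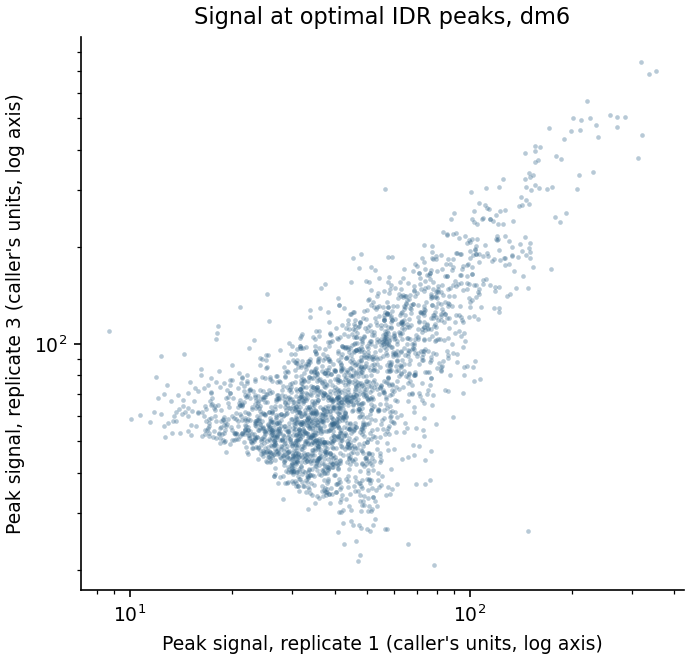
Each point is 1 of the 2419 optimal IDR peaks matched in both replicates, with the authors' peak signal in replicate 1 on the x axis and in replicate 3 on the y axis, both logarithmic. The points rise together with a Spearman rho of 0.563, and the median over peaks of the ratio of replicate 3 to replicate 1 was 1.73.

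The next comparison asked which parts of the genome the peaks lay in. Promoters held 1100 of the 2426 IDR summits (45.3%, 95% Wilson interval 43.4 to 47.3%), with a promoter taken as 500 bp either side of a protein-coding transcription start site (TSS). Shifted summits gave a mean of 11.5%, so promoters were enriched 3.94-fold (two-sided permutation p over shifts = 0.002, the smallest possible, adjusted p = 0.003 over 6 classes). Coding exons held 7 summits against 322 after shifting, a ratio of 0.0218, and 3′ untranslated regions held 18 against 124 (adjusted permutation p = 0.003 for each). Intergenic sequence, here meaning outside protein-coding gene bodies, was also depleted, with 397 summits against 729.9 (adjusted permutation p = 0.003). Introns held 891 summits against 951 (adjusted permutation p = 0.077) and 5′ untranslated regions 13 against 19.3 (adjusted p = 0.194), and neither passed the test. In the top peaks of replicate 1 alone introns did pass, below the shifted mean (ratio 0.91, adjusted permutation p = 0.0168). Each summit has 1 class, so the excess at promoters lowers the counts left for the other classes, and the class tests are not independent. Introns outnumbered intergenic sequence by 951 to 729.9 among shifted summits and by 891 to 397 among IDR summits. A ratio below 1 therefore does not show that introns are avoided outside promoters, and shares outside promoters were not tested. Promoter summits lay mostly upstream of the nearest TSS, 869 of 1100 (79.0%, interval 76.5 to 81.3%), with a median position of -90.5 bp relative to it. Against the pooled-list regions outside the IDR list, of which 26.9% lay in promoters, the enrichment was 1.69-fold (Fisher's exact test, two-sided, p = 9.0e-77). The 2574 regions ranked 2427 to 5000 in the pooled list, a range chosen after the data were seen, had a promoter share of 44.7%, close to that of the IDR peaks.

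**Figure D2:**
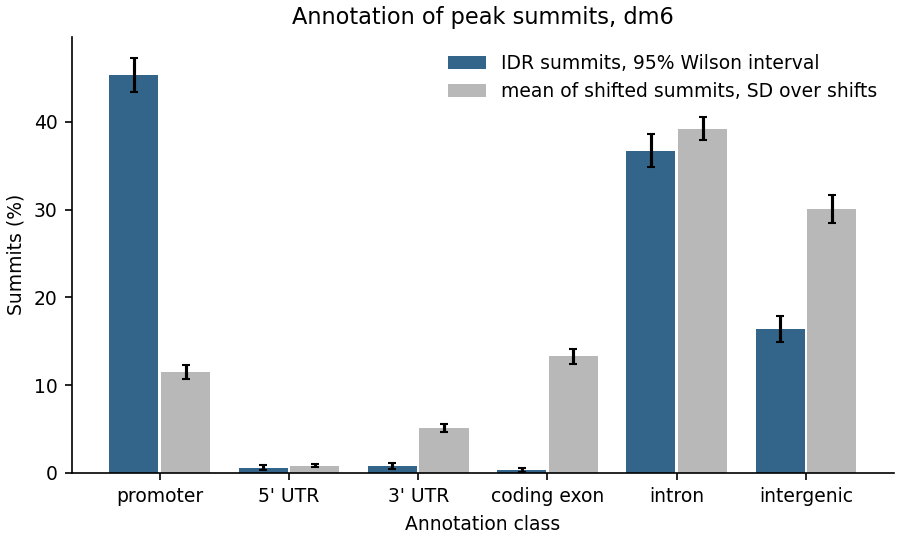
Bars give the percentage of the 2426 IDR summits in each annotation class (blue, with 95% Wilson intervals) and the mean percentage over 1000 circular shifts (grey, with the SD over shifts). Promoters stand at 45.3% against 11.5%, and coding exons at 0.289% against 13.3%.

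Of the 25 strongest IDR peaks, 14 were in promoters, 7 in introns and 4 in intergenic sequence. The promoter peaks included those of px, a wing vein patterning gene (2R 22514103 to 22514504, signal 1055, rank 2), CG14100 (3L 19590429 to 19590810, signal 1023, rank 3), Chro, which encodes a chromodomain protein of interphase chromatin and the spindle (3L 22878728 to 22879102, signal 776, rank 6), and Ugalt, a UDP-galactose transporter gene (X 2703713 to 2704070, signal 771, rank 7). Promoter peaks were also nearest to Art3, the Polycomb group gene ph-p, PNPase, CG1888, CenG1A, gish, mRpL41, Tcs5, CG9147 and CG31145. The peak nearest to Art3 (3R 15229349 to 15229718, signal 731) also lay within 500 bp of the start of mRpS10, and that nearest to CenG1A (2L 13835313 to 13835641, signal 676) within 500 bp of mRpS23, so these peaks count for both neighbours. Intronic peaks were nearest to cbt, CG11050, the kinase gene Lk6, CG3726, the adherens junction gene cno, CG9663 and CG32772, and intergenic peaks to hll, CG13323, CG4004 and the mitotic cyclin gene CycB. The nearest TSS was as far as 11925 bp away, at CG13323. Over all 1326 IDR peaks outside promoters, the median distance to the nearest TSS was 3011 bp.

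The next comparison asked which kinds of genes had a peak at their promoters. Of 13945 protein-coding genes, 1429 (10.2%, 95% Wilson interval 9.75 to 10.8%) had an IDR summit within 500 bp of a TSS. Of 26 gene lists fixed before the data were examined, 5 differed from the other genes after Benjamini-Hochberg adjustment over the lists, 3 with more peaks and 2 with fewer (Fisher's exact test, two-sided). Genes of cytosolic ribosomal proteins stood furthest apart, with peaks at 55 of 86 (64.0%, interval 53.4 to 73.3%) against 9.91% of other genes, an odds ratio of 16.1 (Fisher's exact test, adjusted p = 3.8e-32). The strongest were at RpL7 (2L 10200910 to 10201179, signal 362), RpS27 (3R 25247378 to 25247665, signal 342), RpL13A (3R 5624313 to 5624539, signal 270) and RpLP0 (3L 22075962 to 22076154, signal 244), with summits 8 to 65 bp from a TSS. Peaks among the strongest 2426 of each replicate were at 56 of these genes in replicate 1, 51 in replicate 3 and 46 in both. The odds ratio was 8.25 against genes with any pooled-list region at a promoter and 24.5 with a window of 200 bp, with adjusted p values of Fisher's exact test from 1.2e-40 to 6.3e-19 over the alternatives. By contrast, 10 of 73 genes of mitochondrial ribosomal proteins had a peak (13.7%, Fisher's exact test, adjusted p = 0.654), among them mRpS10 and mRpS23.

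The list named BTB zinc finger genes, which includes CG12236 itself, had peaks at 7 of 20 (35.0%, interval 18.1 to 56.7%, odds ratio 4.73, Fisher's exact test, adjusted p = 0.018). Its members were taken by symbol and their zinc fingers were not examined, so this describes the list and not a protein family. CG12236 is 1 of the 7 with a peak, and without it, tested after the data were seen, 6 of 19 had a peak (odds ratio 4.05, Fisher's exact test, adjusted p = 0.04998, at the threshold). The strongest were at lola (2R 10541810 to 10542233, signal 177), Cp190, which encodes an insulator protein (3R 15275115 to 15275538, signal 165), psq (2R 10557617 to 10558040, signal 124) and Trl, which encodes the GAGA factor (3L 14757000 to 14757423, signal 122). Notch pathway genes had peaks at 7 of 23 (30.4%, interval 15.6 to 50.9%, odds ratio 3.85, Fisher's exact test, adjusted p = 0.034). The strongest were at the co-repressor gene gro (3R 26042400 to 26042628, signal 294), the Notch-responsive genes E(spl)m3-HLH (3R 26021158 to 26021581, signal 198) and E(spl)m7-HLH (3R 26036376 to 26036799, signal 178), and numb, which encodes an inhibitor of Notch (2L 9449479 to 9449902, signal 143). The first 3 are neighbours in the E(spl) complex, and without that complex, tested after the data were seen, 4 of 13 had a peak (30.8%), with an odds ratio as large (3.90) but an adjusted p of 0.137 by Fisher's exact test. In the top peaks of replicate 3 alone, the adjusted p was 0.0587 for BTB zinc finger genes and 0.0983 for the Notch pathway, and further settings also ended both calls, including 1 TSS per gene (0.309 and 0.0843) and a background of genes with any pooled-list region (0.292 and 0.49). Over all alternatives the adjusted p ranged from 0.00265 to 0.309 for BTB zinc finger genes and from 0.00551 to 0.49 for the Notch pathway (Fisher's exact test).

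Chemoreceptor genes had no IDR peak at any of 180 promoters (Wilson upper limit 2.09%, Fisher's exact test, adjusted p = 8.1e-08). Only 16 of them had any pooled-list region there, and against such genes alone the adjusted p was 0.353. The list drawn from histone gene symbols had a peak at 1 of 118, the variant gene His2Av (3R 26866494 to 26866917, signal 151; odds ratio 0.0742, Fisher's exact test, adjusted p = 0.00075). Of its members, 111 lie in the repeated cluster at 2L 21416953 to 21541681, where the pooled list had 0 regions against 30.2 for an average stretch of 2L of that length, and the other 7 include HisRS, HisCl1 and HisT, which are not histone genes. Among those 7 alone the odds ratio was 1.46 (Fisher's exact test, adjusted p = 0.863), so the low count rested on the repeated cluster and cannot be read as depletion.

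The other 21 lists did not pass. Shares above that of other genes, but not past the threshold, were seen by Fisher's exact test for insulator and architectural proteins (5 of 18, adjusted p = 0.115, Chro and Dref strongest), muscle structure and mesoderm (8 of 34, adjusted p = 0.083, Msp300 and sls) and heat shock genes (5 of 23, adjusted p = 0.258, Hsp83 and Hsp26). In the top peaks of replicate 3 alone the insulator list passed (7 of 18, Fisher's exact test, adjusted p = 0.0076), and in those of replicate 1 alone the muscle list passed (9 of 34, adjusted p = 0.0353). The muscle list also passed with each IDR summit at its single nearest TSS (8 of 34, odds ratio 3.84, Fisher's exact test, adjusted p = 0.0127). Chromatin regulators gave 4 of 20 Polycomb group genes (ph-p and Sfmbt) and 4 of 22 trithorax group genes (Utx and fs(1)h). Among patterning genes, peaks were at 1 of 20 members of the list named gap and pair-rule genes. That member was bcd, a maternal gene of neither class. Peaks were also at 2 of 16 segment polarity genes (hh and nkd) and none of 8 Hox genes, where the Wilson upper limit was 32.4%. Cell type lists gave 0 of 24 neuroblast and precursor genes, 2 of 26 neuronal genes (elav and Nrx-1), 2 of 12 glial genes (moody and Gli), 0 of 16 tracheal genes, 1 of 17 haemocyte genes (ush), 3 of 23 genes of endoderm, gut and fat body (fkh and Adh) and 3 of 23 germline genes (bgcn and egl). Growth and housekeeping lists gave 4 of 37 proteasome genes (Rpn5 and Rpn3), 2 of 17 cytosolic tRNA synthetase genes (IleRS and SerRS) and 5 of 37 replication and cell cycle genes (dpa and Dp). There were peaks at 1 of 11 dosage compensation genes (Sxl) and 0 of 17 chorion and vitelline membrane genes. These lists are small, and apart from the insulator and muscle lists their Wilson intervals include the share of other genes.

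**Figure D3:**
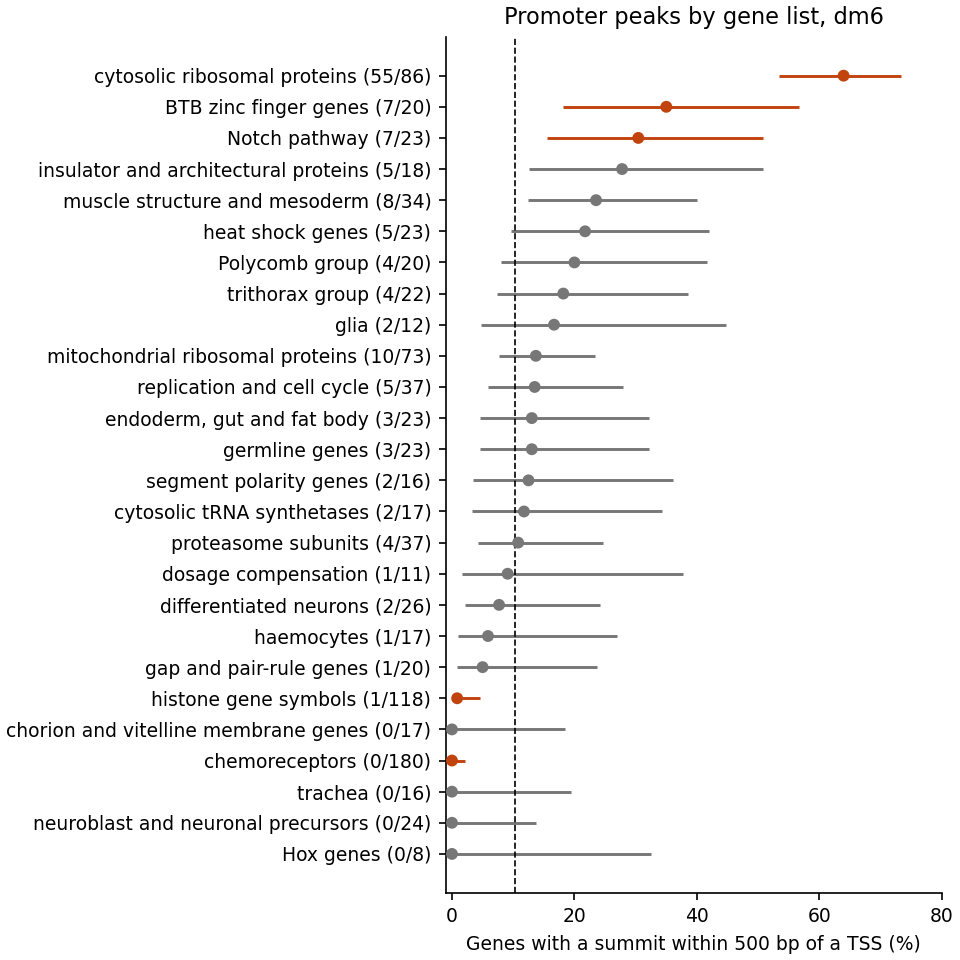
Points give the percentage of genes in each fixed list with an IDR summit within 500 bp of a TSS, with 95% Wilson intervals and counts beside the names. Red marks the 5 lists past an adjusted p of 0.05, and the dashed line is the 10.2% of all protein-coding genes.

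A further comparison set the X chromosome against the autosomes, since a pool of both sexes carries on average fewer X than autosome copies. Peaks were at 193 of 2196 X-linked genes (8.79%) and 1232 of 11669 genes on 2L, 2R, 3L and 3R (10.6%), an odds ratio of 0.816 (Fisher's exact test, two-sided, p = 0.011). The single arms ranged from 9.85% on 2R to 11.0% on 3R, and chromosome 4 had 4 of 80 genes. In the top peaks of replicate 3 alone the odds ratio was 0.891 (Fisher's exact test, p = 0.152), and with a TSS window of 1000 bp it was 0.885 (p = 0.096). The odds ratio was lower with a window of 200 bp (0.633, Fisher's exact test, p = 5.9e-06), 1 TSS per gene (0.745, p = 0.0008) and the top peaks of replicate 1 alone (0.721, p = 5.5e-05).

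Sequence motifs were compared between IDR summits and 7896 weaker regions of the pooled list matched for promoter class and GC content. The GAGA motif, bound by the Trl product, occurred within 100 bp of 116 of 2426 summits (4.78%) against 3.03% of matched regions (odds ratio 1.61, Fisher's exact test, adjusted p = 0.0015 over 21 motifs). The core promoter element Ohler motif 7 occurred at 291 summits (12%) against 9.83% (odds ratio 1.25, Fisher's exact test, adjusted p = 0.027), and the Adf1-like motif was rarer, at 2.89% against 4.09% (odds ratio 0.697, adjusted p = 0.044). The other 18 motifs did not pass, among them the DRE (odds ratio 1.07, Fisher's exact test, adjusted p = 0.892). The DRE passed against sequence 1000 bp to either side, which was not matched for promoter class (odds ratio 5.67, Fisher's exact test, adjusted p = 1.1e-16), and against pooled regions ranked below 15000 (1.57, 0.035). Its adjusted p ranged from 1.1e-16 to 1 over the alternatives, by Fisher's exact test. In the top peaks of replicate 1 alone, the CTCF core (odds ratio 1.44, Fisher's exact test, adjusted p = 0.031) and the E-box of Ohler motif 5 (1.23, 0.038) also passed. In the 1213 strongest IDR peaks the CTCF core passed too (1.84, Fisher's exact test, adjusted p = 0.0088), and the initiator was rarer (0.777, 0.0229). Of 32441 8-mers tested within 50 bp of a summit, 0 passed the adjusted threshold on chromosome 2, where 995 had an unadjusted Fisher p under 0.05. When the 20 best were retested on chromosomes 3, X and 4, 1 passed: CACTGTGC, at 29 of 1492 summits (1.94%) against 0.814% of matched regions (odds ratio 2.42, Fisher's exact test, adjusted p = 0.0097). The GAGA call ended within 50 bp (Fisher's exact test, adjusted p = 0.459), against sequence 1000 bp to either side (0.679) and in the 1213 strongest peaks (0.102), and the motif 7 call ended within 50 bp (0.459) and in the 1213 strongest peaks (0.817). The Adf1-like call ended in the top peaks of replicate 3 alone (0.0581) and of replicate 1 alone (0.634). CACTGTGC passed the retest in the top peaks of replicate 3 alone but was not among the 4 words that passed in those of replicate 1 alone.

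At CG12236 itself (X 5908135 to 5913079, forward strand), 1 IDR peak lay at the promoter. Its interval was X 5907895 to 5908318, with a summit 28 bp before the gene start, a pooled signal of 80.4, a saturated −log10 q of 3.82 and rank 1949. The nearest summits ranked 905 in replicate 1 (signal 47.4) and 3289 in replicate 3 (signal 37.1). The pooled list had 2 further regions within 1000 bp of the gene, at X 5907333 to 5907756 (signal 23.4, rank 17417) and X 5912459 to 5912882 (signal 39.2, rank 6760), outside the IDR list. A far stronger peak lay nearby in an intron of CG3726 (X 5918740 to 5919093, signal 710.1, rank 11). The transgene carries CG12236, so reads from the transgene and from the native gene cannot be separated here.

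**Figure D4:**
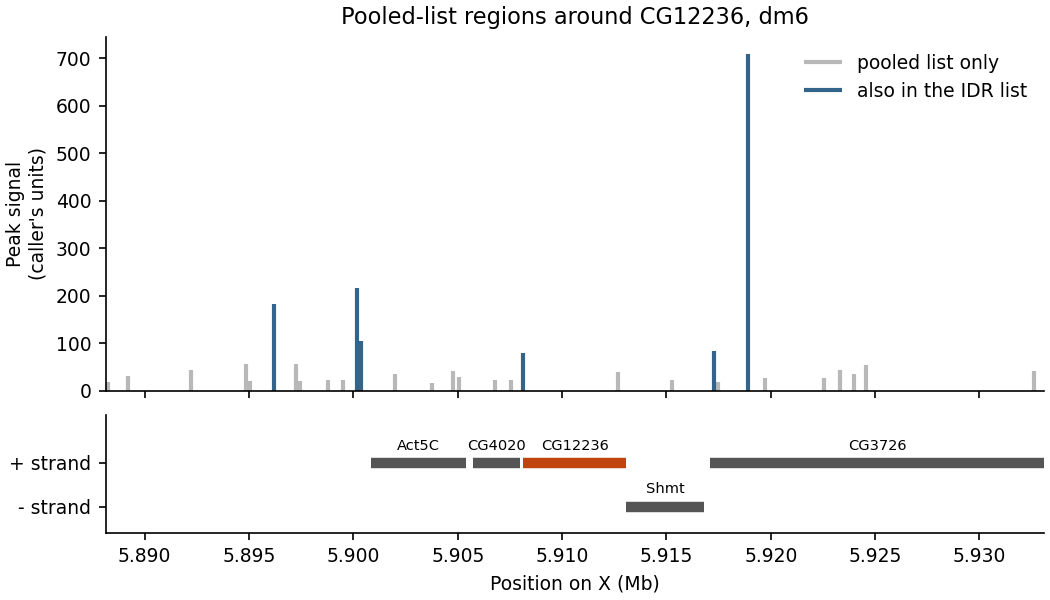
Vertical lines give the authors' signal of each pooled-list region at its summit on X (Mb, dm6), blue for regions also in the IDR list and grey for the rest, above the protein-coding genes on each strand. The CG12236 promoter peak has a signal of 80.4, and the peak in CG3726 reaches 710.1.

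The same experiment was also given on the older assembly dm3, from separate alignments. The dm3 IDR list held 2288 peaks against 2426 on dm6, with fewer or equal numbers on every arm, for example 448 against 469 on 2L and 11 against 11 on chromosome 4. On 2L, 440 IDR summits had exactly the same position on both assemblies, and their signal on dm6 was a median of 1.00 times that on dm3 (range 0.995 to 1.01).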

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

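On dm3, some regions lay on sequences outside the 6 main arms, which no comparison above used. There were 43 in the pooled list, 42 in that of replicate 1 and 58 in that of replicate 3, with no control list analysed beside them. Most of the pooled ones were on 3LHet (12), 3RHet (11) and XHet (8), which hold heterochromatin assembled apart from the arms. The strongest, on 3RHet, had a signal of 46.9 and ranked 4837, and 0 of these regions were in the dm3 IDR list.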

How the results depend on the processing

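The alternatives with weaker background regions, wider 8-mer windows, all arms together, changed list members or symbols as written were chosen after the data were seen. Replicate overlap (61.0 to 71.3%), replicate correlation (rho 0.563 to 0.609) and promoter enrichment (1.69- to 6.29-fold) kept their direction and call in every alternative run, and 4 or 5 annotation classes passed in each. The 1.69-fold enrichment was against all pooled-list regions outside the IDR list. Those ranked 2427 to 5000 were not used alone as an alternative, and 44.7% of them lay in promoters, against 45.3% of IDR summits. The ribosomal protein list passed in all 9 alternatives run on it, with odds ratios from 8.25 to 24.5. The X against autosome odds ratio lost its call with a 1000 bp window (0.885) and in the top peaks of replicate 3 alone (0.891). It was 0.721 in those of replicate 1 alone. The number of lists past the threshold was 5, and fell to 2 in the 1213 strongest peaks, 3 with 1 start site per gene and 1 against genes with any pooled-list region. It was 4 to 6 in single replicates. BTB zinc finger genes missed the threshold in the 1213 strongest peaks (odds ratio 4.31), with 1 start site per gene (2.58), against genes with any pooled-list region (3.17) and in the top peaks of replicate 3 alone (3.86). They stood at it without CG12236 (4.05) and passed in the top peaks of replicate 1 alone (4.53). The Notch pathway missed the threshold with a 200 bp window (2.76), in the 1213 strongest peaks (3.63), with 1 start site per gene (3.64), against genes with any pooled-list region (2.19) and without the E(spl) complex (3.90). It also missed it in the top peaks of replicate 3 alone (3.18) and passed in those of replicate 1 alone (3.68). Against genes with any pooled-list region the chemoreceptors (0) missed the threshold too. The histone list missed it in the 1213 strongest peaks (0.145) and turned to 1.01 against genes with any pooled-list region and to 1.46 without the repeated cluster. With a 200 bp window the ratios of 5′ untranslated regions (1.12) and introns (1.05) turned above 1, both without a call before or after. Of 21 motifs, 3 passed, against 1 within 50 bp, 8 against flanking sequence and 5 against regions ranked below 15000. GAGA missed the threshold within 50 bp (1.31), against flanking sequence (1.05) and in the 1213 strongest peaks (1.47), motif 7 within 50 bp (1.11) and in the 1213 strongest peaks (1.099), and the Adf1-like motif in single replicates (0.706 to 0.904). The number of 8-mers past the retest was 1, against 16 with flanking controls, 4 with regions ranked below 15000 and 15 within 100 bp, and 2 to 4 in single replicates. CACTGTGC was among them in the top peaks of replicate 3 but not in those of replicate 1. Several of the 15 words within 100 bp overlap in sequence, so their number is not one of separate elements. The cause was not tested, except for the 8-mer window, which is taken up in the other observations. Read depth is unknown, so no limit from it can be given. No paired analysis was possible because there is only 1 group.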

Other observations

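The tests in the first paragraph here, the inner and outer word windows, the word test over all arms and the direct test of abundant against ribosomal protein genes were chosen only after results were seen, while the other tests were written down once their pattern was known but before their own values. IDR peaks at promoters were placed differently from weaker regions at promoters. Of 1100 IDR promoter summits, 79.0% lay upstream of the nearest TSS, against 50.6% of 7419 promoter regions outside the IDR list (odds ratio 3.67, Fisher's exact test, p = 5.2e-74), and the median positions were -90.5 bp and -3 bp relative to it. Weaker regions can have less exact summits, which was not tested. Promoters with start sites of different genes on both strands made up 34.4% of the IDR promoter peaks and 19.8% of the others (odds ratio 2.12, Fisher's exact test, p = 1.4e-25). A summit between start sites that point apart is upstream of the nearer one, so both differences are not independent. The regions outside the IDR list also include some right beside IDR peaks. Of 8 pairs of ribosomal protein genes whose symbols differ in a last a or b, 6 had a peak at only 1 copy, as at RpS5a but not RpS5b, RpS19a but not RpS19b, and RpS10b but not RpS10a. RpL34a and RpL34b both had a peak, and RpL10Aa and RpL10Ab had none. Of the 70 ribosomal protein genes outside such pairs, 47 had a peak (67.1%). The number of pairs expected to have a peak at only 1 copy was not computed. Reads shared between similar copies were not examined either, so the pairs do not show a preference for 1 copy. Outside protein-coding genes, IDR summits lay within 200 bp of 4 of 290 tRNA genes, 1 of 269 snoRNA genes, 2 of 32 snRNA genes, 0 of 99 rRNA genes and 138 of 3261 genes annotated as ncRNA (4.23%). Repeats among these genes can limit such counts, which was not tested.

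Ribosomal protein promoters held peaks far more often than other promoters. Shared promoters argue little for it, since giving each summit to its single nearest TSS raised the odds ratio to 22.1, and neither replicate alone carries it, with an adjusted p of 5.7e-28 or lower in each. General recovery of DNA at highly transcribed genes remains a candidate explanation. It was examined with a list of 37 other genes picked for abundant transcripts, whose expression was not measured here. Translation genes such as eEF1gamma are among them, so the list cannot separate high transcription from a preference for such genes. Of the 37, 15 had a peak (40.5%, Wilson interval 26.3 to 56.5%), among them eEF1gamma, Gapdh2 and Hsp83. That interval lies above the 9.83% of the remaining genes, a condition added to the prediction when it was computed, and overlaps the one of the ribosomal protein genes, 53.4 to 73.3%, although a direct test put the abundant genes lower (odds ratio 0.384, Fisher's exact test, p = 0.018). Other housekeeping lists were near the share of other genes, with peaks at 13.7% of mitochondrial ribosomal protein, 10.8% of proteasome and 11.8% of cytosolic tRNA synthetase genes. Their transcription was not measured, so they do not decide the question. No control list was analysed, so a preference of the protein itself for these promoters was not tested.

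Few motifs separated the IDR peaks from background regions, and no 8-mer did in the first step on chromosome 2, although over all arms together CACTGTGC did (50 of 2426 against 62 of 7896, odds ratio 2.66, Fisher's exact test, adjusted p = 0.027). If summits were placed too loosely for a 50 bp window, words should pass the first step in windows of 100 bp, and 13 did. CACTGAGA led them (5.25% against 1.12%, Fisher's exact test, adjusted p = 1.5e-07), and CACTGTGC was among them (4.39% against 1.36%, adjusted p = 0.0026). Several of the 13 overlap, such as ACACTGAG, CACTGAGA and ACTGAGAG, so they are not separate elements. On the retest chromosomes the 13 words were at 12.2% of summits against 4.88% of background regions between 50 and 100 bp (odds ratio 2.71), and at 8.04% against 4.79% within 50 bp (odds ratio 1.74). The 13 words were picked on chromosome 2 in windows of 100 bp, where 0 words had passed within 50 bp. That choice favours words lying farther out, so the larger outer enrichment cannot argue for or against loosely placed summits. The wider window also holds more sequence, which raises the power whatever the cause, so the prediction cannot decide the question. Whether weaker true sites among the background hide words stays open: controls ranked below 15000 raised the enriched motifs from 2 to 4, yet 0 words passed, with 3003 controls.

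The strong peak in CG3726 beside CG12236 lies in a stretch dense in regions. From 20 kb before to 20 kb after the gene there were 30 pooled-list regions, above the percentile limit of 24 among 4682 overlapping windows of that length on X, while their median signal of 34.8, above the 23.8 of a usual window, was below its limit of 42.6. Extra copies of the region from the transgene could raise both, so this explanation cannot be told apart from a stretch dense in peaks for other reasons: the number of regions passed its limit and the signal, although raised, did not. No biological explanation was tested.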
